A study of Mus musculus with 2 samples.

How the data were processed

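The series holds 2 droplet-based single-cell RNA-seq libraries of LSK cells, sorted bone-marrow cells that lack lineage markers and carry Sca-1 and c-Kit. Per the labels, 1 library came from mice on low-fat food (LFD, 10% of energy as fat) and 1 from mice on high-fat food (HFD, 60%), both after 24 weeks. Per the file headers and values, each deposited matrix holds raw UMI counts (unique molecular identifiers, each standing for 1 captured transcript) of 32286 features in unfiltered barcodes, 1880618 in the LFD and 1698912 in the HFD library. The submitters' processing notes name Cell Ranger 6.2.1 and the mm10 build, while the file headers read Cell Ranger 4. The kit version also differs between the series text and the sample labels. The features include an eGFP sequence, which entered no comparison.

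Cells were called in each library as barcodes with at least 1/10 of the 99th percentile of UMI totals among the 3000 largest barcodes, which gave a minimum of 5966 UMIs in the LFD and 5680 in the HFD library. This called 8052 and 7522 barcodes. Of these, 5 and 2 had fewer than 500 genes, and 32 and 38 more had over 10% mitochondrial UMIs. Doublets were called with scrublet (scanpy 1.11.5). Its automatic threshold did not work: it marked 1 of 8015 LFD cells and 0 of 7482 HFD cells. Removing the 6% of cells with the highest scores was therefore added as an alternative. The comparisons used 8014 LFD and 7482 HFD cells. Below the minimum, 1563 LFD and 1087 HFD barcodes held over 2000 UMIs.

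The 15496 cells were normalised to 10000 UMIs per cell, log-transformed and clustered together without integration (2000 variable genes, of which 1877 remained after leaving out cell cycle, immediate early, heat shock, interferon, ribosomal, mitochondrial and globin genes and Xist; 30 principal components, 15 neighbours, Leiden resolution 0.8, seed 0). A cluster was called X-like only when at least 3 fixed markers of 1 cell type were at least 2 times higher than in the other cells (after adding 5 CPM), with a median log2 difference of at least 0.3, and at least 2 of them stood among its top 10 genes. This named 11 of 17 clusters. A class is the set of clusters with 1 name. Class shares are given with exact (Clopper-Pearson) 95% binomial intervals, and ratios of shares with intervals from the log ratio. Without a replicate library, no test across libraries, p-value or number of changed genes is given, and every interval covers counting error only.

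For genes, UMIs were summed over the cells of a library or class and scaled to the UMI total of that library or class (CPM), and the HFD/LFD ratio was given with its exact conditional binomial 95% interval. A value against a count of 0 was computed at a floor of 3 counts. Values at the same class weights average the CPM of 7 classes (those with at least 20 cells in each library, unnamed clusters as 1 class) with the mean share of the libraries as weight. Gene groups were 28 fixed lists and 12 marker lists with 815 genes, of which 813 are in the files (Mx1 and Mx2 are not among the features). Members with at least 50 UMIs in both libraries together counted as measured. Counts of members higher or lower give the side of each ratio only, also where its interval includes no difference. Each list has its median log2 ratio and the percentile of that median among 10000 random lists of the same size, matched on mean CPM in 20 bins. The lists cover lineage markers, cell cycle, signalling, stress, metabolism, transcription factors and sort markers. Over the 14329 genes with enough UMIs, the median log2 ratio was 0.04. Classes with at least 100 cells in each library were compared, which left 6.

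The rule for named genes took the 15 highest and 15 lowest ratios in all cells, and the 5 highest and 5 lowest in each class. It required 200 UMIs in total and 20 CPM where higher, and left out gene models, clone names, mitochondrial, cytosolic and mitochondrial ribosomal protein and globin genes and genes with over 2 times the CPM in empty droplets. It also took up to 4 members per list. Identifiers are those of the files, and mm10 positions come from the GENCODE vM21 annotation by identifier, which matched 32158 of them.

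Cell cycle shares were computed in cells thinned to 6464 UMIs, which left out 481 LFD and 747 HFD cells. A cell counted as S list positive with at least 0.3% of its UMIs in the S phase list, and as G2 and M list positive with at least 0.5%. Free RNA was measured in barcodes with 10 to 100 UMIs, 44788 in the LFD and 41267 in the HFD library. A list's CPM in a class over its CPM in these barcodes is an upper limit of the free RNA share of that class. In the HSC-like class immunoglobulin genes gave 2.47% (LFD) and 3.21% (HFD), the share used for subtraction; of the other 4 gene sets, globin genes gave 18.6% and 29.5%, and mature neutrophil genes 6.48% and 2.16%. Immunoglobulin genes were taken as the tightest limit in the LFD library after the values were seen. In the HFD library mature neutrophil genes set a lower limit than the share subtracted. The share of the HSC-like class was also subtracted in every other class. In HFD megakaryocyte-like and erythroid-like cells mature neutrophil genes gave limits of 1.43% and 0.589%. Values with free RNA subtracted can therefore be corrected too far.

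The interval and list steps were tested on simulated data for the comparison of summed UMIs over 12353 genes. The interval held the true ratio for 95.3% of 12153 unchanged genes and lay on the true side for 92% of 50 genes changed 1.25 times and 100% of those changed 1.5 times. Of 200 lists without a difference, 5.5% fell outside the central 95 percentiles. The simulation drew each gene on its own with counting error only, which the interval assumes. It held no UMIs gathered in few cells and no genes that vary together. It therefore checks the computation and cannot show the coverage for the real counts. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

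Groups, lists, markers, the named-gene rule and most alternatives were chosen before the data were examined. Other choices came after. The number of markers required among the top 10 genes was raised from 1 to 2 once clusters had been named against their leading genes. The limits of the cell cycle shares were set on the distribution of list shares. The functional lists that lead the account (median of at least 0.2 in size, at least 10 measured members, outside the central 95 percentiles) were chosen with the medians known; at 0.25 in place of 0.2 the unfolded protein response and lymphoid transcription factors would drop out. Alternatives changed the UMI minimum, mitochondrial limit, doublets, clustering, depth, free RNA, scaling, count filter, class and cluster weights and weight of cells, 1 at a time.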

Results

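LSK cells, the sorted bone-marrow fraction that holds haematopoietic stem cells (HSC) and multipotent progenitors, were profiled in 1 library from male C57Bl6/J mice on low-fat food (LFD) and 1 library from mice on high-fat food (HFD). The LFD library held 127508561 UMIs and the HFD library 114880392, of which 85.4% and 86.5% lay in barcodes called as cells. The 8014 LFD cells had a median of 10387.5 UMIs and 3189 genes, and the 7482 HFD cells a median of 10102.5 UMIs and 3226 genes. The mitochondrial share had a median of 4.14% in the LFD and 4.50% in the HFD library. How many mice went into each library is not given in the sources used here.

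The comparison asks how stem and progenitor cells of mice on high-fat food differ from those of mice on low-fat food. The HFD library held a smaller share of HSC-like cells (32.4% against 40.3%). The clusters of this class did not move together: clusters 12 and 1 had smaller shares (log2 ratios -2.08 and -0.94), and cluster 2 a larger one (0.61). The share of megakaryocyte-like cells was smaller too (3.92% against 6.86%, but 13.9% against 14.6% at Leiden resolution 0.5). The share of cells primed towards neutrophils and monocytes was larger (6.28% against 3.53%). The HSC-like class holds its clusters in other proportions in each library. Within it, Slamf1, which encodes the stem-cell surface receptor CD150, had a log2 ratio of -1.73 (-0.82 with the same cluster weights). Flt3, a receptor of multipotent and lymphoid-primed progenitors, had one of 1.33 (0.64). In both libraries, cluster 2 had more Flt3 and less Slamf1 than clusters 1 and 12. Over all cells, the granule genes Elane and Mpo of the neutrophil lineage had log2 ratios of 1.39 and 1.11, which were 0.50 and 0.24 with the same class weights, and all 10 MHC class II genes were higher, with a median log2 ratio of 0.48 (0.30 without B, T-NK and monocyte-dendritic-like cells, and -0.58 in neutrophil-monocyte-primed-like cells). In each of 6 compared classes the clock gene Per1, the chemokine receptor gene Cxcr4 and Myc were higher, and the cold-inducible Cirbp and Mid1 were lower. These 5 were picked out for this after their values were seen. Such agreement is common, since 1730 of 6885 genes with enough UMIs in each class lay on 1 side in all 6. The classes come from the same 2 libraries. With 1 library per diet no difference has a replicate check, so each describes these libraries. The share of lymphoid-primed-like cells turned direction with the clustering.

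The neutrophil-monocyte-primed-like class, with top genes that include Elane, Mpo, Ctsg and Ms4a3, was at 3.53% (95% interval 3.14 to 3.96) of LFD and 6.28% (5.74 to 6.86) of HFD cells, a 1.78-fold difference (1.54 to 2.05). When cells were clustered without the defining genes that differed between the libraries, it was 2.63% and 5.01%, and with the UMI minimum doubled the log2 ratio went from 0.83 to 1.44. The HSC-like class, with Hlf, Procr, Sult1a1 and Meg3 among the top genes of its clusters, held 40.3% (39.3 to 41.4) of LFD and 32.4% (31.4 to 33.5) of HFD cells, and 40.1% and 29.9% without those genes, but 5.56% and 1.65% in thinned cells, most of which stayed unnamed; with the excluded lists kept among the variable genes its log2 ratio went from -0.32 to -1.06. Cluster 1 held most HSC-like cells of the LFD library (53.4%) and cluster 2 most of those of the HFD library (61.2%). As shares of all cells, clusters 1 and 12 were lower in the HFD library (log2 ratios -0.94 and -2.08) and cluster 2 was higher (0.61). In cluster 2, 4 of 16 detected HSC markers were at least 2 times higher than in the other cells. In clusters 1 and 12 these were 16 of 17 and 15 of 18. Flt3 was at 77.6 (LFD) and 121 CPM (HFD) in cluster 2, against 13.3 and 21.2 CPM in cluster 1. Slamf1 was at 6.95 and 2.26 CPM in cluster 2, against 31.2 and 14.9 CPM in cluster 1. The class name thus covers unlike clusters. The megakaryocyte-like class, led by Pf4, Itga2b and Treml1, held 6.86% (6.32 to 7.44) and 3.92% (3.49 to 4.38), and 5.19% and 3.39% without those genes. At Leiden resolution 0.5 it was 14.6% and 13.9%. The erythroid-like class, with Car1, Klf1 and Ermap, held 4.70% and 3.62%, and 4.69% and 3.66% without them. HSC-like cells were shallow, with a median of 7876 UMIs (LFD) and 7416 (HFD) close to the UMI minimum of a cell, while erythroid-like cells had medians of 37932 and 39407, a depth at which doublets are to be weighed.

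Lymphoid-primed-like cells, with Flt3, Satb1 and Il12a among their top genes, made up 7.08% (6.52 to 7.66) of LFD and 10.6% (9.91 to 11.3) of HFD cells. Without the differing defining genes they were 15.7% and 16.6%, and with cells thinned to 1 depth the log2 ratio was -0.07. At Leiden resolution 0.5 they were 14.0% and 21.9%. Cluster 6, led by Ccr9, Wfdc17 and Ccl5, stayed unnamed under the marker rule and held 3.78% of LFD and 9.70% of HFD cells. Its Flt3 was at 313 and 354 CPM and its Satb1 at 295 and 286 CPM. In lymphoid-primed-like cluster 5 these were at 218 and 231 CPM and at 212 and 226 CPM. Wfdc17, Wfdc18 and Cd33 were top genes of both clusters. Cluster 13, led by histone genes, Spp1 and Dntt, held 2.10% and 2.15%. Had 1 marker among the top 10 genes been enough, cluster 6 would have been T-NK-innate lymphoid-like and that class 4.02% and 9.97%, and cluster 13 lymphoid-primed-like and that class 9.17% and 12.8%. All 6 unnamed clusters together held 34.4% and 40.5%, and 5 of these had S phase, histone or mitotic genes among their top genes. B cell-like cells were 2.80% and 1.87% (0.811% and 0.388% without the differing genes). Cluster 14, led by genes of B cell precursors such as Ebf1, Vpreb3 and Igll1, held 71.0% of them in the LFD and 79.3% in the HFD library, and cluster 15, led by Igkc, Jchain and Igha, the rest. Within cluster 14 Ebf1, Vpreb3 and Igll1 had log2 ratios of 2.17, 2.17 and 2.39, so its name rests more on its HFD cells. At Leiden resolution 0.5 B cell-like cells were 0.898% and 0.735%. T-NK-innate lymphoid-like cells were 0.237% and 0.267%, and monocyte-dendritic-like cells, with Cd74, Xcr1 and Naaa, were 1 LFD cell and 37 HFD cells. All but 1 of its cells came from the HFD library, so the cluster describes that library. With the UMI minimum doubled, the class of this name held 125 LFD and 200 HFD cells (3.79% and 6.19%). A higher minimum adds no cells, so most cells of that class had other names in the main clustering. It therefore does not show whether the near absence from the LFD library holds. The class held 1 LFD and 32 HFD cells after thinning, and 3 and 44 with the highest 6% of doublet scores removed.

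**Figure D1:**
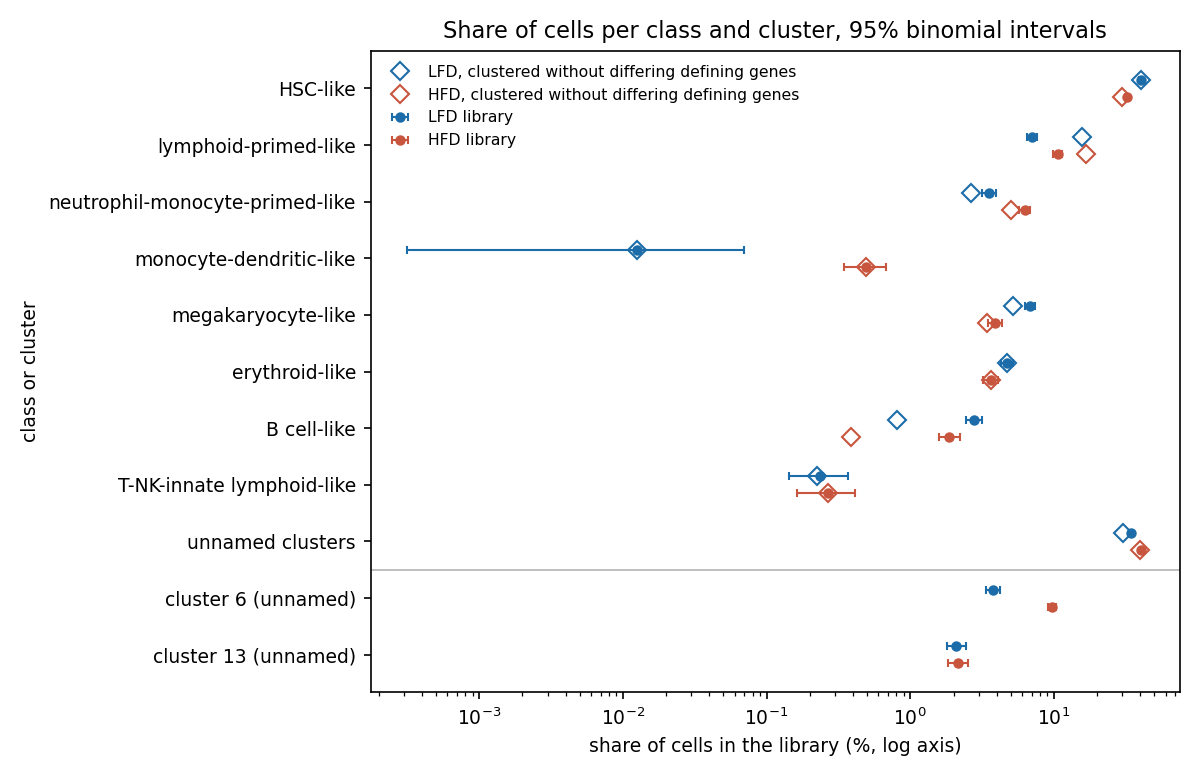
Share of cells (percent, log axis) in each named class and in unnamed clusters 6 and 13, for the LFD (blue) and HFD (red) libraries; filled points have exact 95% binomial intervals, and open diamonds are shares when clustered without the defining genes that differed between libraries. HSC-like, megakaryocyte-like and erythroid-like shares were lower and the neutrophil-monocyte-primed-like share higher in the HFD library in both clusterings.

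Over all cells, genes of the neutrophil and monocyte lineage led the higher side. Elane (ENSMUSG00000020125, chromosome 10, 79886247 to 79888215), which encodes neutrophil elastase, was at 443 CPM in the LFD and 1160 CPM in the HFD library, a log2 ratio of 1.39 (1.37 to 1.40). Mpo, myeloperoxidase, had a log2 ratio of 1.11, Ctsg, cathepsin G, 1.00, and Cebpe, a transcription factor of granulocyte maturation, 1.65. Fcgr3 and Trem3 were at 1.46 and 1.44. Over 90% of the UMIs of these 6 genes in the HFD library came from the neutrophil-monocyte-primed-like class, whose defining genes Elane, Mpo, Ctsg and Cebpe are. With the same class weights in both libraries their log2 ratios were 0.50 for Elane, 0.24 for Mpo, 0.11 for Ctsg, 0.78 for Cebpe, 0.51 for Fcgr3 and 0.54 for Trem3. Prg2, an eosinophil granule gene, was at 2.47, with 87.1% of its HFD UMIs in 5 cells.

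Per1 (ENSMUSG00000020893, chromosome 11, 69095217 to 69109960) was at 10.5 and 26.8 CPM, a 2.55-fold difference (2.38 to 2.74) and a log2 ratio of 1.35, and at 1.49 with the same class weights. Cd69, an early activation marker of lymphocytes, was at 17.9 and 40.9 CPM (1.19), Gfi1, a repressor needed in stem cells and granulocyte progenitors, at 15.8 and 31.3 (0.98), and Rhob at 24.3 and 47.8 (0.98). Cd74, the MHC class II invariant chain, was at 148 and 286 CPM, with 33.3% of its HFD UMIs in the 37 monocyte-dendritic-like cells. Rgcc (0.93) and Gpr65 (0.91) completed the higher side, with Ighg3 at 4 and 2621 UMIs, 98.6% of the latter in 5 cells.

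On the lower side, Cavin2 (ENSMUSG00000045954, chromosome 1, 51289126 to 51302960) was at 39.9 CPM in the LFD and 12.4 CPM in the HFD library, a log2 ratio of -1.69 (-1.78 to -1.60). Pf4, platelet factor 4, was at 191 and 81.8 CPM (-1.22) and at -0.56 with the same class weights. Genes with more of their LFD UMIs in HSC-like cells than in any other class were also lower: Nupr1 (-1.24), Sult1a1 (-1.20), Clec1a (-1.05), Mllt3, a regulator of stem-cell maintenance (-0.81), Cdkn1c, which encodes the cell cycle inhibitor p57 (-0.78), and Bex4 (-0.77). Mid1 was at -1.17 and Ubash3b at -0.90. The remaining lower genes were immunoglobulin genes of few cells: Iglc3 (-4.57, 94.3% of LFD UMIs in 5 cells), Iglc2 (-3.67, 84.0% in 5 cells), Igkc (-1.28), Jchain (-1.03) and Igha (-0.85, and -0.32 with the same class weights).

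**Figure D2:**
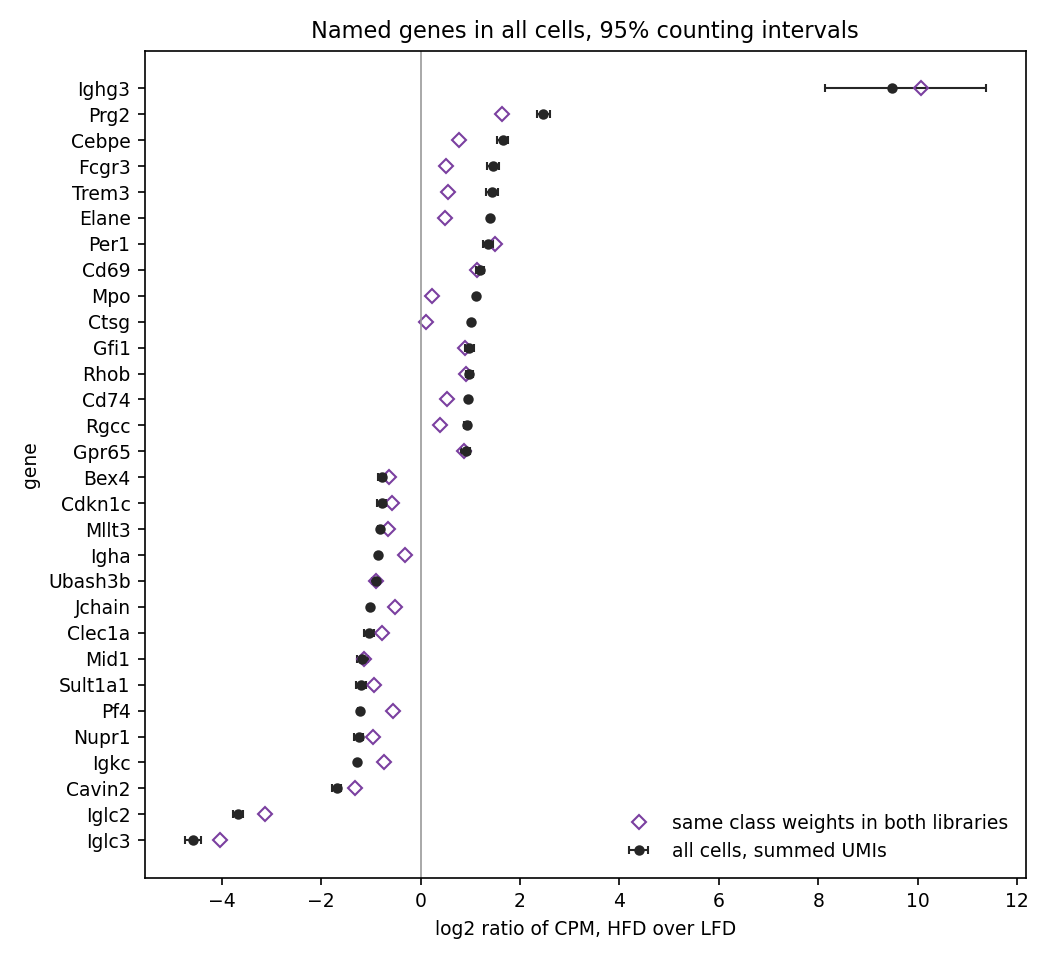
Log2 ratio of CPM (HFD over LFD) of the 30 named genes in all cells; filled points are summed UMIs with 95% counting intervals, and open diamonds use the same class weights in both libraries. Elane lay at 1.39 and at 0.50 with the same class weights, while Per1 lay at 1.35 and 1.49.

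Of the lineage marker lists, all 17 neutrophil-monocyte-primed markers were higher in the HFD library, with a median log2 ratio of 0.83 (above all 10000 random lists), led by Fcnb (3.82), Cebpe and Hp (1.53). At the same class weights the median was 0.24. All 16 lymphoid-primed markers were higher, with a median of 0.31 (0.28 at the same class weights), among them Rag1 (1.11), Flt3 (0.57) and Blnk (0.55). Of 15 megakaryocyte markers 13 were lower, with a median of -0.65, and -0.42 at the same class weights, among them Vwf (-1.55) and Gp1bb (-1.40). Of 18 HSC markers 15 were lower (median -0.36, and -0.17 at the same class weights), led by Meg3 (-1.40), Clca3a1 (-1.36) and Hoxb5 (-0.97), and of 19 erythroid markers 18 were lower (-0.26, and -0.08), among them Gfi1b (-0.75) and Apoe (-0.77). Mature neutrophil markers had a median of 1.81 (0.95 at the same class weights), with S100a8 at 16.2 and 135 CPM, and macrophage markers 1.10 (0.69), with Vcam1 at 1.17 and 7.99 CPM. Monocyte-dendritic markers had a median of 0.68 (0.17 at the same class weights), mast-basophil-eosinophil markers 0.24 (-0.17 at the same class weights), B cell markers -0.36 (-0.0037 at the same class weights), T-NK-innate lymphoid markers 0.18 (-0.03 with the UMI minimum doubled) and endothelial-stromal markers -0.20 (0.03 with at least 500 UMIs per gene).

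Among the functional lists, 6 had the larger medians. MHC class II genes were higher in 10 of 10 (median log2 ratio 0.48), with Cd74 (0.95), H2-Eb1 (0.91) and H2-Aa (0.77), and the median was 0.30 without B, T-NK and monocyte-dendritic-like cells. Myeloid transcription factors were higher in 11 of 12 (0.60, and 0.28 at the same class weights), with Cebpe, Klf4 (1.04), Gfi1 and Myc (63.0 and 116 CPM, 0.89). Immediate early genes, which respond to stimulation within minutes, were higher in 17 of 19 (0.27, and 0.14 with at most 5% mitochondrial UMIs), with Fos at 0.94. Inflammatory signalling genes were higher in 21 of 26 (0.25): Bcl3 (0.80) and Tnfaip3 (0.80), feedback regulators of NF-kB, were higher and the chemokine gene Cxcl2 was lower (-1.41). Unfolded protein response genes were higher in 21 of 24 (0.25), with the chaperone gene Hspa5 at 0.54 and Sdf2l1 at 0.72. Lymphoid transcription factors were higher in 12 of 17 (0.21), with Ebf1 at 1.36 and Satb1 at 0.42. The medians of these 6 lists lay at or above the 99.96th percentile of random lists. Of the stress genes, Hspa1a (-1.30) and Hspa1b (2.38-fold) were lower while Hsph1 (0.84) was higher, and 12 of 16 heat shock genes were higher (0.15).

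Metabolic lists differed less. Fatty acid synthesis genes were higher in 11 of 17 (0.18, 98.6th percentile), with Fasn, fatty acid synthase, at 24.8 and 35.9 CPM (0.53), Elovl5 at 0.64 and Scd1 at -0.78. Cholesterol synthesis genes were lower in 13 of 22 (-0.05, 0.69th percentile). Fatty acid oxidation and PPAR target genes were split, 15 higher and 16 lower (median -0.0031), although Acot1, an acyl-CoA thioesterase, was at 24.7 and 45.0 CPM (0.86). Oxidative phosphorylation had a median of 0.01 (-0.03 when centred on the median gene), with Uqcrq of complex III at 0.67, and glycolysis 0.07. Sterol efflux genes had a median of 0.09, with Apoe at 265 and 155 CPM. Nutrient and adipokine receptors were higher in 18 of 20 (0.20), with Cxcr4 (0.86) and Vldlr (0.71). Antioxidant genes had a median of 0.02, p53 targets 0.15, autophagy and lysosome genes 0.12, TGF-beta signalling 0.11, quiescence and self-renewal regulators 0.07, interferon response 0.06, with Isg15 at -0.55, and MHC class I 0.09. Cytosolic ribosome genes were lower in 58 of 60 by a small amount (-0.08). Megakaryocyte and erythroid transcription factors were lower in 10 of 13 (-0.11). Mitochondrial transcripts had a median of 0.0047, sort gate genes 0.08 and globin genes -0.14 (0.14 at the same class weights).

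**Figure D3:**
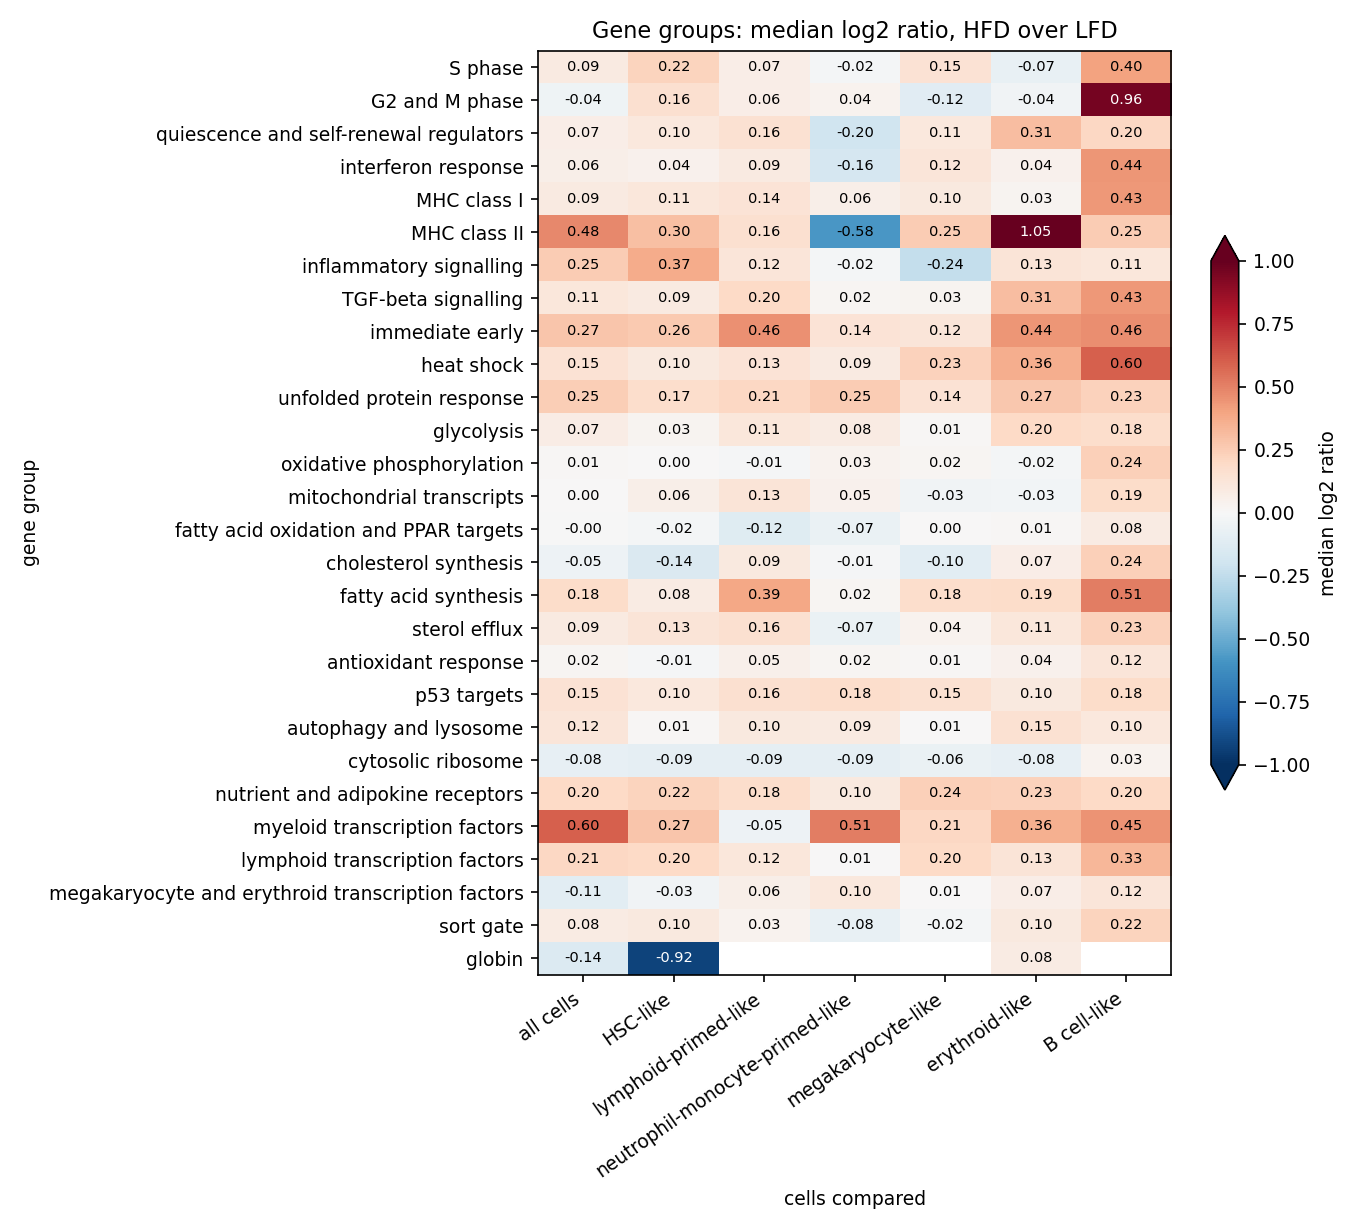
Median log2 ratio (HFD over LFD) of the measured members of each fixed functional list, in all cells and in 6 classes; colours end at -1 and 1, and empty fields had too few measured members. Immediate early genes were at 0.26 in HSC-like and at 0.46 in lymphoid-primed-like cells.

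Within the HSC-like class, some genes of long-term stem cells and of the platelet-biased state were lower in the HFD library, in part through its mix of clusters. Slamf1 was at 29.8 and 8.95 CPM (log2 ratio -1.73, -1.98 to -1.50), Clu at 23.3 and 5.80 (-2.00), Gadd45g at -1.83, the metallothionein gene Mt1 at -1.74 and Calml4 at -1.72, and Vwf was 2.93-fold lower (-1.55). Within cluster 12, which has Vwf among its top genes, Vwf was at 148 and 151 CPM, and in clusters 1 and 2 it was lower in the HFD library (27.8 and 15.7 CPM in cluster 1). Of 18 HSC markers 13 were lower (median -0.28), with Clca3a1 at -1.56 and Meg3 at -1.07, and 11 of 14 megakaryocyte markers (-0.49), beside 12 of 16 erythroid markers (-0.41), globin genes (3 of 4, -0.92) and 3 of 5 endothelial-stromal markers (-1.09, and -0.25 without a minimum count). On the higher side were Cd69 (1.48), Per1 (1.40), Flt3 (33.1 and 83.5 CPM, 1.33), Gfi1 (1.27), Cxcr4 (2.38-fold), Satb1 (1.24) and Myc (1.19). The lymphoid-primed markers (11 of 11, 0.34) and the neutrophil-monocyte-primed markers (14 of 16, 0.64, and 0.25 with free RNA subtracted) were higher. The share subtracted in the HFD library is above its limit from mature neutrophil genes, so 0.25 may be too low. Inflammatory signalling (0.37), MHC class II (0.30), myeloid transcription factors (0.27), immediate early genes (0.26) and S phase genes (37 of 42, 0.22) were higher too. The HSC-like class mixes 3 clusters in other proportions in each library. With the same cluster weights, Per1 was at 1.54, Cd69 at 1.28, Flt3 at 0.64, Slamf1 at -0.82, Gadd45g at -1.09 and Clu, a defining gene of cluster 12, at -0.54, and the HSC marker median was 0.03. The medians of megakaryocyte (-0.24), lymphoid-primed (0.10) and neutrophil-monocyte-primed markers (0.31), inflammatory signalling (0.24) and S phase genes (0.08) were smaller in size as well.

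**Figure D4:**
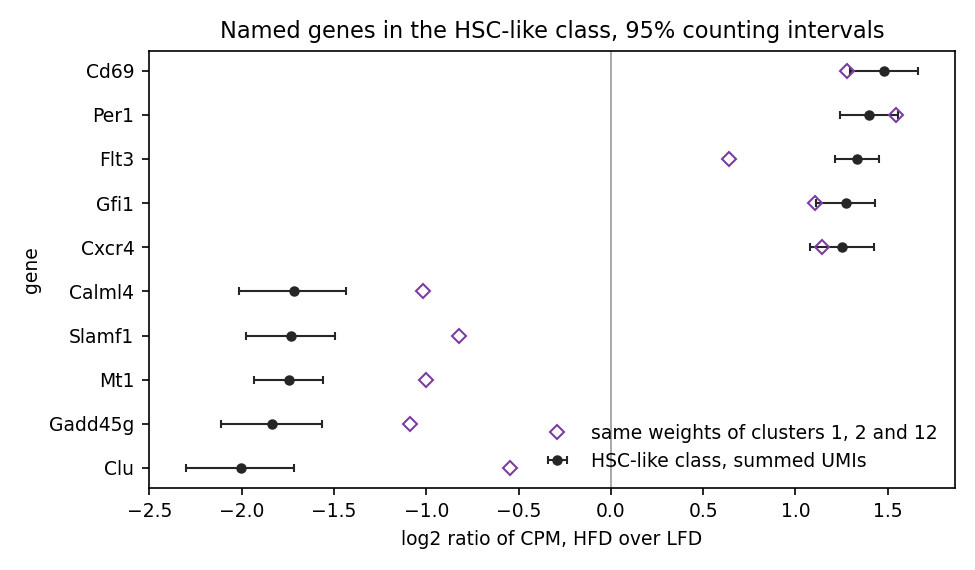
Log2 ratio of CPM (HFD over LFD) of the named genes of the HSC-like class; filled points are summed UMIs with 95% counting intervals, and open diamonds use the same weights of clusters 1, 2 and 12 in both libraries. Slamf1 lay at -1.73 and at -0.82 with the same cluster weights.

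In the neutrophil-monocyte-primed-like class, some genes of later granulocyte stages were higher. S100a8, a calprotectin subunit, was at 215 and 983 CPM (2.19), Fcnb at 2.88 and Cebpe at 104 and 179 CPM (0.78), and mature neutrophil markers were higher in 7 of 10 (median 0.88), with the other 3 lower. Some of these rest on few cells: 5 cells held 31.7% of the HFD UMIs of S100a8, 87.7% of those of Chil3 (4.29), 96.6% of those of Prg2 (4.14) and 74.3% of those of Prg3 (1.54). Averaged per cell, the mature neutrophil median was -0.15. MHC class II genes were lower in 8 of 9 (-0.58), with Cd74 at 85.2 and 36.9 CPM (-1.21) and H2-Aa at -1.07; 5 cells held 73.9% of the LFD UMIs of Cd74. Fcer1a (-1.08), Csrp3 (-1.06) and Hspa1b (-1.33) were also lower, with 55.3%, 43.3% and 19.9% of their LFD UMIs in 5 cells.

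In the lymphoid-primed-like class, Per1 was at 6.33 and 26.2 CPM (2.05), Tmem158 at 1.11, Hsph1 at 1.02, Mettl3 at 0.96 and Tsc22d3, a glucocorticoid-induced leucine zipper gene, at 0.96. Mid1 (-1.47), Ubash3b (-1.03), Bex6 (-0.83), Shld2 (-0.74) and Rsrp1 (-0.73) were lower, and immediate early genes were higher in 15 of 16 (0.46). In the megakaryocyte-like class Cish, a target of cytokine signalling, was at 1.16, Cxcr4 at 1.00, Hsph1 at 1.00, Banp at 0.90 and Usp38 at 0.90, while Slamf1 (2.37-fold), Ckap2l (-1.01), Mt1 (-0.91), Gadd45g (-0.89), Vipas39 (-0.87) and 12 of 15 megakaryocyte markers (-0.23) were lower. Lymphoid-primed markers (10 of 10, 0.25) and neutrophil-monocyte-primed markers (9 of 11, 0.51, and 0.29 with free RNA subtracted) were on the higher side there. These counts give the side of each ratio only. The share subtracted is above the free RNA limit of this class, so 0.29 may be too low.

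In the erythroid-like class Vcam1 had 0 LFD and 427 HFD UMIs, 196-fold higher at a floor of 3 counts (lower counting bound 159-fold). These lay in 24 cells with 67.9% in 5 of them, and macrophage markers had a median of 5.26. Psap (1.26), Selenop (1.21), Nfkbia (1.19) and Per1 (1.13) were higher there, and Ppp1r9a (-2.02), Isg15 (-1.21), Hist1h2bc (-0.92), Mid1 (-0.82) and Klf3 (-0.63) lower. In the B cell-like class some of the higher genes describe few cells: Igll1 (2.70, 54.9% of HFD UMIs in 5 cells) and Vpreb2 (2.46, 35.1% in 5 cells), parts of the surrogate light chain of B cell precursors, Ighg2c (2.29, 99.8% of HFD UMIs in 5 cells), Ighg3 (2 cells) and Ighv1-69 (0 and 236 UMIs, 1 cell). Igkv12-46 (-5.99, -8.27 to -4.43, 71.2% of LFD UMIs in 5 cells), Iglc3 (-4.06, 95.3% in 5 cells), Iglc2 (-3.16, 85.3%), Igkv12-44 (-1.91, 2 cells) and Iglv1 (-1.60, 55.4%) were lower. G2 and M phase genes were higher in 45 of 45 there (0.96), in a class where most lists lie above 0, with oxidative phosphorylation at 0.24 (42 of 45).

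In all cells, S phase genes were higher in 28 of 42 (median 0.09), with Ccne2, the cyclin E2 gene, at 0.47 and Mcm2, a replication helicase gene, at 0.38, and G2 and M phase genes were lower in 35 of 52 (-0.04), with Ckap2l at -0.29. In thinned cells the S list share was 37.0% (35.9 to 38.1) in the LFD and 42.8% (41.6 to 44.0) in the HFD library, and 35.3% and 39.3% without thinning. Thinning kept 2838 of 3233 LFD and 1920 of 2426 HFD HSC-like cells, few of which are S list positive. Leaving out more of them in the HFD library can widen the difference. These shares over all cells also depend on the class proportions of each library. The G2 and M list share was 32.7% and 34.1%, within counting error, and 31.1% and 31.0% without thinning. In HSC-like cells the S list share was 3.35% (2.72 to 4.08) and 5.52% (4.54 to 6.64), and 2.72% and 4.91% without thinning, but with the UMI minimum doubled it was 12.2% and 10.3%. In megakaryocyte-like cells it was 59.6% and 74.4%. In the unnamed clusters, which hold most of the S list positive cells, it was 58.3% and 56.9%, and the G2 and M list share was 68.4% and 58.3%, but these clusters had other proportions in each library, with 303 LFD and 726 HFD cells in cluster 6. Phase calls, which free RNA can move too, put 22.2% of LFD and 27.5% of HFD thinned cells in S phase.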

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

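In this part, the tests of free RNA, of swapped molecules, of the sort gate and of a UMI minimum of 2000 were chosen or rewritten only after the result was seen, the last with its limits set before its value was known; the test of depth alone was not. The first free RNA test of eGFP used other limits, and the sort gate test, whose first form met both of its opposite conditions, was divided by class with the values known.

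Reads of eGFP, a feature outside every comparison, gave 215 UMIs in LFD and 338 in HFD cells (1.98 and 3.42 CPM, against 2.86 and 4.83 CPM in empty droplets), although the labels name C57Bl6/J mice. They lay mostly in neutrophil-monocyte-primed-like cells, where 29.0% of LFD and 32.6% of HFD cells had a UMI, against 0.897% and 1.36% of HSC-like cells and 0% (at most 0.974%) and 0.738% of erythroid-like cells, which had the higher median depth. The tables argue against free RNA (CPM in that class 4.20 times that of empty droplets in the lower library), against molecules swapped in from another library (80.2% of eGFP UMIs in called cells in the lower library) and against depth alone (classes at least 25.5 times apart). A sequence shared with a myeloid transcript or a reporter may be the source, and neither was tested, nor was any biological explanation.

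MHC class II genes had a median log2 ratio of 0.30 in HSC-like and 1.05 in erythroid-like cells but -0.58 in neutrophil-monocyte-primed-like cells. In the erythroid-like class macrophage (5.26), monocyte-dendritic (1.26) and neutrophil-monocyte-primed markers (1.07, and 0.38 with free RNA subtracted) were higher as well, and in the neutrophil-monocyte-primed-like class 5 cells held 73.9% of the LFD UMIs of Cd74. The share subtracted is above the free RNA limit of HFD erythroid-like cells, so 0.38 may be too low. The difference between the classes was not tested.

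The HFD library had lower HSC-like and megakaryocyte-like shares and a higher neutrophil-monocyte-primed-like share, with a lymphoid-primed-like share that turned direction with the clustering. A UMI minimum that loses shallow cells is argued against, but only weakly. At 2000 UMIs the log2 ratio of the HSC-like share was -0.63, but a new clustering run moves this ratio as well. With seed 1 and unchanged cells it was -0.60, and with the minimum doubled it was -0.19. Free RNA is argued against too, at most 3.21% of UMIs by immunoglobulin genes. A shifted Sca-1 or c-Kit gate stays open for all of these shares: in megakaryocyte-like cells Ly6a was at -0.092 (-0.32 to 0.13), and in HSC-like and lymphoid-primed-like cells expression within the class does not show how many other cells a gate let in. For the neutrophil-monocyte-primed-like share Ly6a was lower (-0.88, -1.20 to -0.57), as a gate that let in cells with less Sca-1 would give. More mature cells in the class could give it too. Ly6a RNA was low in this class in both libraries, at 23.7 (LFD) and 12.9 CPM (HFD). In erythroid-like cells it was at 8.70 and 12.1 CPM, in megakaryocyte-like cells at 70.5 and 66.1, and in HSC-like cluster 1 at 244 and 251. Kit was at 160 and 158 CPM in megakaryocyte-like and at 79.4 and 78.5 CPM in neutrophil-monocyte-primed-like cells. Its RNA thus shows little difference in these classes. The diet itself stays open and untested, since each diet has 1 library.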

How the results depend on the processing

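Alternatives chosen after the data were seen were the UMI minimum of 2000, removal of the highest 6% of doublet scores, unscaled genes, clustering without differing defining genes or without cycle-correlated genes, the same cluster weights, leaving out rare mature cells and names from 1 marker. No paired analysis was possible because each diet has 1 library. The HSC-like, neutrophil-monocyte-primed-like and erythroid-like shares kept their direction in 15 of 15 alternatives (log2 ratios -1.75 to -0.19, 0.83 to 1.44 and -0.47 to -0.20), and the megakaryocyte-like share in 14 of 14 (-1.38 to -0.06). The lymphoid-primed-like share kept it in 10 of 12. The megakaryocyte-like name covered sets of cells of unlike size, so its agreement in direction is not that of 1 fixed set. It held 550 LFD and 293 HFD cells in the main clustering. These were 1167 and 1043 at Leiden resolution 0.5, and 75 and 38 with seed 1. Names from 1 marker left the HSC-like, neutrophil-monocyte-primed-like, erythroid-like and megakaryocyte-like shares at their main values, so that alternative tests nothing for these. Each of the 6 leading functional lists kept its direction in 12 of 12. Keeping doublet calls added 1 LFD cell and left all 40 group and 30 gene values in all cells within counting error. It tests nothing for these values, though they are counted below. Of the 113 values of class shares, 72 were within counting error, 38 moved and 3 turned; of the 300 values of genes in all cells, 204, 96 and 0; of the 377 values of genes within classes, 273, 104 and 0; of the 480 values of groups in all cells, 360, 111 and 9; of the 485 values of groups within classes, 348, 134 and 3; of the 35 cell cycle values, 24, 10 and 1. In all cells, the UMI minimum of 2000 gave the same S list and G2 and M list shares as keeping doublet calls, since added cells were too shallow to be thinned, so it tests nothing for these 2 values. A value counts as turned when its direction changes and its first interval lies on 1 side of no difference; the G2 and M list share in all cells, whose interval does not, kept its direction in 4 of 6. Unless said otherwise, the cause was not tested.

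Log2 ratios of shares are given in the order named. At Leiden resolution 0.5 the megakaryocyte-like share was at -0.063. At 1.2 the HSC-like and lymphoid-primed-like shares were at -0.50 and 0.40. With seed 1 the HSC-like share was at -0.60. With the excluded lists kept, HSC-like, lymphoid-primed-like and neutrophil-monocyte-primed-like shares were at -1.06, 0.26 and 1.08. With unscaled genes the HSC-like share was at -0.67 and the B cell-like share turned to 0.14. Without differing defining genes the HSC-like and lymphoid-primed-like shares were at -0.43 and 0.084, and without cycle-correlated genes at -0.76 and 0.088. With clusters from the LFD library alone, HSC-like, lymphoid-primed-like, neutrophil-monocyte-primed-like and megakaryocyte-like shares were at -0.56, 0.22, 1.09 and -1.38. In thinned cells the HSC-like share was at -1.75 (5.56% and 1.65%, with 73.5% and 77.6% of cells unnamed), the lymphoid-primed-like share turned to -0.071 and the neutrophil-monocyte-primed-like share was at 1.09. With doublet calls kept, a change of 1 cell, the HSC-like share was at -0.39, the lymphoid-primed-like share turned to -0.015 and the megakaryocyte-like share was at -0.35, which shows how far 1 clustering run moves them. With the highest 6% of doublet scores removed, HSC-like and megakaryocyte-like shares were at -0.38 and -0.25. At 2000 UMIs the HSC-like and lymphoid-primed-like shares were at -0.63 and 0.16.

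With the UMI minimum doubled, HSC-like, lymphoid-primed-like, neutrophil-monocyte-primed-like and megakaryocyte-like shares were at -0.19, 0.022, 1.44 and -1.21; inflammatory signalling, immediate early, unfolded protein response, myeloid and lymphoid transcription factors at 0.18, 0.37, 0.32, 0.76 and 0.14; the S list and G2 and M list shares at 0.067 and -0.022. The S list share of HSC-like cells turned to -0.24 and T-NK-innate lymphoid markers to -0.033. With at most 5% mitochondrial UMIs the same 4 shares were at -0.86, 0.35, 1.12 and -0.48, the same 5 lists at 0.20, 0.14, 0.29, 0.47 and 0.14 and the 2 cell cycle shares at 0.27 and 0.13, and mast-basophil-eosinophil markers of lymphoid-primed-like cells turned to 0.0025.

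Centred on the median gene, inflammatory signalling, unfolded protein response and lymphoid transcription factors were at 0.21, 0.21 and 0.17, and oxidative phosphorylation turned to -0.031. With 500 UMIs per gene, mast-basophil-eosinophil and endothelial-stromal markers turned to -0.046 and 0.029. At the same class weights MHC class II, immediate early, unfolded protein response, myeloid and lymphoid transcription factors were at 0.32, 0.36, 0.17, 0.28 and 0.24, and oxidative phosphorylation, globin and mast-basophil-eosinophil markers turned to -0.017, 0.14 and -0.17. At the same cluster weights HSC markers of HSC-like cells turned to 0.031. Averaged per cell, MHC class II, unfolded protein response, myeloid and lymphoid transcription factors were at 0.60, 0.21, 0.39 and 0.28, globin and mast-basophil-eosinophil markers turned to 0.068 and -0.00051, and mature neutrophil markers of neutrophil-monocyte-primed-like cells to -0.15. Without rare mature cells, MHC class II and lymphoid transcription factors were at 0.30 and 0.15. No lymphoid-primed-like class was found with seed 1, unscaled genes or the highest doublet scores removed, and no megakaryocyte-like class with the excluded lists kept.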

Other observations

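In this part, the choice of genes on 1 side in every class came only after the result was seen; the tests of time of day, glucocorticoid exposure and temperature were written before theirs.

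The counts that follow give the side of each ratio only, and some members lie within counting error. In lymphoid-primed-like cells, unfolded protein response genes were on the higher side in 24 of 24 (median log2 ratio 0.21), fatty acid synthesis genes in 10 of 13 (0.39) and HSC markers in 10 of 12 (0.30), while neutrophil-monocyte-primed markers were on the lower side in 10 of 14 (-0.23). In neutrophil-monocyte-primed-like cells, unfolded protein response genes were higher in 20 of 23 (0.25) and interferon response genes lower in 22 of 33 (-0.16), with HSC markers lower in 10 of 12 (-0.44) and monocyte-dendritic markers in 13 of 15 (-0.32). In megakaryocyte-like cells most S phase genes (38 of 42, median 0.15) and heat shock genes (12 of 15, 0.23) were on the higher side. In erythroid-like cells heat shock genes (13 of 15, 0.36) and immediate early genes (12 of 13, 0.44) were higher, beside the macrophage genes of few cells.

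Per1 and Tsc22d3 were higher and Cirbp lower in each of the 6 classes, with Cirbp between -0.82 and -0.53. Of 6885 genes with enough UMIs in each class, 1730 lay on 1 side in all 6, so being on 1 side is not rare by itself. Time of day is argued against, but only weakly. The clock genes that peak with Per1 and Dbp (median 0.27) and those that peak with Arntl (0.29) differed by -0.022 (-0.20 to 0.14). A shift that raises Per1 would be expected to part them. The lists hold only 8 and 5 measured genes, and the interval covers counting error only. Both lists lay on the higher side, in 7 of 8 (98.1st percentile) and 5 of 5 (96.1st percentile). Glucocorticoid exposure stays open, with glucocorticoid-induced genes at 0.14 (9 of 10 higher, 93.4th percentile), and so does cell temperature during handling, with the cold-induced Rbm3 at -0.19 (-0.20 to -0.18). Either may contribute, and the diet stays open as an untested biological explanation, since each diet was handled as 1 library.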
